A study of Caenorhabditis elegans with 36 samples.

How the data were processed

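Small RNA was prepared from total RNA of whole N2 hermaphrodites with the TruSeq small RNA kit, per the labels' protocols, and 36 libraries were sequenced, 3 in each of 12 groups. The counts were made and deposited by the authors as raw read counts per miRNA hairpin, in 1 table of 250 hairpins over all libraries, with no arms separated and 0 rows that name no miRNA. Per the submitters' processing notes the tools were bcl2fastq 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9. The genome build, the miRNA annotation and the treatment of reads that match several hairpins are not given in the sources used here, so counts of near-identical hairpins are uncertain and no coordinates are printed. The kit has no molecular identifiers named in the labels, so intervals on counts cover counting error only.

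Libraries were assigned to groups from the labels of treatment (rotenone at 100 nM, DMSO at 0.1 % or H2O at 0.1 %) and time (6 hours and 1, 2, 3 and 5 days), and replicate numbers only name libraries. The labels also give the sequencing lane, 1 per group on 4 lanes. DMSO at 6 hours and rotenone at 1 and 3 days were on lane 8, rotenone at 6 hours and DMSO at 2 and 5 days on lane 1, DMSO at 1 day, rotenone at 2 days and H2O at 5 days on lane 2, and H2O at 1 day, DMSO at 3 days and rotenone at 5 days on lane 3. Total counts ran from 4361246 to 14960062 per library, which gives 3 counts the weight of 0.688 to 0.201 CPM. No pair of libraries of a group was alike within sampling noise: the chi-square of their counts per degree of freedom ran from 19.4 to 436, so each counted as 1 sample.

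In R 4.3.3, counts were filtered with filterByExpr by group at a minimum count of 10, which kept 193 hairpins of the 241 with at least 1 count. The 57 left out hold 0.00073% of all counts. Counts were scaled with TMM (factors 0.854 to 1.16) and all 36 libraries were fitted in 1 quasi-likelihood model with a mean per group in edgeR 4.0.16, with 24 residual and 12.6 prior degrees of freedom and a common biological coefficient of variation of 0.068. Tests of rotenone against DMSO at each time, of their mean, of their difference between times, of DMSO against H2O, and of time were taken from this fit. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. CPM values use the TMM factors, and log values in the principal components a prior count of 2.

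The groups, comparisons, tests, miRNA lists, the rule for naming miRNAs and the alternatives given here were fixed before the data were examined, and later additions are named as such where they are reported. Named are the 10 largest rises and 10 largest falls among miRNAs past the threshold whose libraries do not overlap between groups (for averaged comparisons, whose group means differ in the same direction each time), or the 10 smallest p-values of an F-test. Where under 5 miRNAs passed, the 5 smallest p-values are named. Named as well are lifespan-associated miRNAs past the threshold, the tissue markers mir-1 (muscle), mir-60 (intestine) and mir-228 (glia), and up to 4 members of a list with the smallest p.

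The 13 lists were the let-7, lin-4, mir-35, mir-51, mir-58, mir-44, mir-2, mir-64 and mir-72 families, lifespan-associated miRNAs (lin-4, mir-34, mir-71, mir-80, mir-238, mir-239a, mir-239b and mir-246), stress-associated miRNAs (mir-34, mir-71, mir-80, mir-239a, mir-239b, mir-246, mir-64, mir-65, mir-66 and mir-229), mirtrons and miRNAs restricted to neurons (mir-124, lsy-6, mir-790 and mir-791). Of their members mir-58 and mir-1834 matched no hairpin name in the table and mir-1019 fell below the filter. Lists were tested with fry on voom values of the same model (limma 3.58.1), adjusted over the 13 lists. fry tests whether the members move on balance in 1 direction and does not compare them with other miRNAs. camera, which compares the members with the other miRNAs and estimates their correlation from the data, was the alternative. Adjusted p-values given below with an estimated correlation are those of camera. They differ from those of fry in the question asked as well as in the correlation. The calls camera kept were the let-7 family at 1 day, the stress-associated miRNAs at 5 days and the same list for 5 against 2 days in DMSO.

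The procedure was tested on simulated counts for the comparison at 2 days, with 45 of 193 hairpins changed in each of 20 simulations. It recovered 59.7% of changes of 1.25-fold, 77% of 1.5-fold and 91.7% of 2-fold, with 4.7% false among its calls, and an unchanged comparison gave 0.05 calls on average. The simulated counts held no differences between lanes or cultures, and their changes took random directions. These rates therefore do not cover errors from lanes or from changes mostly in 1 direction. Alternatives were DESeq2 size factors or total counts in place of TMM, no filter, DESeq2 1.42.0, the replicate number as a block, only the groups compared in the fit, each library left out in turn, an additive model with lane, H2O in place of DMSO, and camera in place of fry. Other splits of the libraries were counted exhaustively where there are 10, and 100 were used elsewhere.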

Results

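Small RNA was sequenced from whole hermaphrodites of N2, the wild-type strain of the nematode Caenorhabditis elegans, after treatment with rotenone, an inhibitor of mitochondrial complex I, or with its vehicle DMSO. Rotenone (100 nM) and DMSO (0.1 %) libraries were made at 6 hours and at 1, 2, 3 and 5 days, and libraries of worms given H2O (0.1 %) at 1 and 5 days, with 3 libraries in each of the 12 groups. The series title counts these times from treatment, while the sample labels enter them as age. The table held raw counts for 250 miRNA hairpins, not split into arms, and 193 hairpins with enough counts were tested. Total counts per library ran from 4361246 to 14960062. The libraries of DMSO at 5 days held 4361246 to 6040997 counts and those of rotenone at 6 hours 11840458 to 14960062. The mir-58 family, the bantam-like miRNAs, took between 28% ± 0.27 (SD, n = 3) of all counts, in DMSO at 2 days, and 34.4% ± 1.1, in rotenone at 5 days. On the first principal component, which held 46.4% of the variance, the 6 libraries of 6 hours lay between -13.15 and -11.34 and the other 30 between -1.345 and 4.956. The second (25%) placed the libraries of 5 days between 5.175 and 6.533 and those of 1 and 2 days between -5.832 and -2.816.

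Each group was sequenced on a single lane, and the rotenone and DMSO groups of every time were on different lanes, so each difference between treatments within a time is also one between lanes. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Values below are log2 fold changes ± SE with n = 3 libraries per group, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. For every miRNA named as changed between 1 group and another, the 3 libraries of 1 group all lay above the 3 of the other, except where stated. This does not hold for comparisons averaged over times or treatments. Hairpins of nearly identical sequence, as within the let-7, mir-35, mir-44 and mir-58 families, can share reads, so the division of counts among such members is uncertain. Such members may also not be separate measurements when members of a list are counted. mir-44 and mir-45, for example, had means of 18340 and 18480 CPM in DMSO at 6 hours and 28070 and 27520 at 2 days.

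At 6 hours the miRNAs that passed the test were mostly lower with rotenone. Among them were members of the mir-35 family, which is abundant in oocytes and embryos: mir-41 fell to 0.64 of its DMSO level (log2 -0.64 ± 0.10, adjusted p = 1.73e-05). mir-1829b fell to 0.748 (log2 -0.42 ± 0.064, adjusted p = 1.73e-05), mir-74 to 0.764 (log2 -0.39 ± 0.065, adjusted p = 4.02e-05) and mir-2209a to 0.749 (log2 -0.42 ± 0.084, adjusted p = 0.000847). mir-243, a miRNA that associates with the RNA interference Argonaute RDE-1, fell to 0.799 (log2 -0.32 ± 0.068, adjusted p = 0.00118), and mir-355 to 0.793 (log2 -0.34 ± 0.073, adjusted p = 0.00142). Both miRNAs that rose did so by little: mir-238, whose loss shortens lifespan, by 1.13-fold (log2 0.18 ± 0.059, adjusted p = 0.0431) and mir-59 (log2 0.20 ± 0.062, adjusted p = 0.0313), which was named after its values were seen and whose groups overlapped.

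In all, 23 of the 193 miRNAs passed at 6 hours, 2 higher and 21 lower with rotenone, and 42 (21.8%) had groups that did not overlap, where chance gives 10%. In the mir-35 family 5 of 8 members fell (7 adjusted over the list alone), and the set test fry gave an adjusted p of 0.00558. The test camera, which asks whether a list differs from the other miRNAs, gave an adjusted p of 0.792 with an estimated correlation. Adjusted p-values with an estimated correlation are from camera throughout. Of the 5 members that fell, mir-38 (-0.36 ± 0.11), mir-35 (-0.31 ± 0.10) and mir-39 (-0.24 ± 0.079) had overlapping groups, and 1 member fell under either other scaling. The family took 2.46% ± 0.052 of all counts in DMSO and 2.16% ± 0.52 in rotenone (SD, n = 3). The glial marker mir-228 stood at -0.30 ± 0.11 (adjusted p = 0.0541). In the mir-72 family 2 of 3 members fell (2 adjusted over the list alone; fry adjusted p = 0.00558, adjusted p = 0.905 with an estimated correlation), mir-74 and mir-72 (log2 -0.18 ± 0.050, adjusted p = 0.0214). In the mir-51 family, whose members are broadly expressed, mir-51 (-0.21 ± 0.071) and mir-54 (-0.21 ± 0.056) fell (2 adjusted over the list alone; fry adjusted p = 0.0411, adjusted p = 0.907 with an estimated correlation). mir-229 (log2 -0.16 ± 0.048, adjusted p = 0.0255) was the member of the mir-64 family and of the stress-associated miRNAs that fell (1 adjusted over either list alone). fry gave 0.0411 and 0.00558 for these lists, adjusted p = 0.907 for both with an estimated correlation, and their direction turned to a rise with total counts in place of TMM. mir-8190 had 2 counts in rotenone against 13 in DMSO, a ratio of 0.0992 after scaling (95% counting interval 0.0109 to 0.438). Its DMSO libraries were uneven, at 0.51 ± 0.63 CPM (SD, n = 3), and the interval does not cover that spread. With total counts fry passed none of these 5 lists, and with size factors the mir-35 and mir-72 families (adjusted p = 0.0477 for both). With total counts 10 miRNAs passed, 5 higher and 5 lower, with DESeq2 size factors 13 (3 and 10), and without the filter on low counts 8. An edgeR fit of these 6 libraries alone passed 0 (24 at an unadjusted p under 0.05). DESeq2, fitted to all 36 libraries and not to these 6, called 20. Leaving out DMSO replicate 1, 2 or 3 or rotenone replicate 1 left 13, 10, 13 or 12.

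At 1 day the let-7 family, which includes heterochronic miRNAs that time larval development, was higher with rotenone. let-7 rose 1.29-fold (log2 0.37 ± 0.056, adjusted p = 1.57e-05), mir-241 1.31-fold (log2 0.39 ± 0.090, adjusted p = 0.00192) and mir-795 1.28-fold (log2 0.35 ± 0.074, adjusted p = 0.00114). mir-34, which responds to DNA damage and affects stress resistance and lifespan, rose 1.21-fold (log2 0.27 ± 0.051, adjusted p = 0.000298), from 658 ± 9.82 CPM (counts scaled to a common library size; SD, n = 3) in DMSO to 795 ± 14.2. mir-799 rose 1.42-fold (log2 0.50 ± 0.13, adjusted p = 0.0045), and mir-72 1.23-fold (log2 0.30 ± 0.050, adjusted p = 7.76e-05). mir-235, which holds progenitor cells quiescent in starved larvae, rose 1.31-fold (log2 0.39 ± 0.095, adjusted p = 0.00325). mir-244 fell to 0.723 of its DMSO level (log2 -0.47 ± 0.083, adjusted p = 0.000127) and mir-67 to 0.757 (log2 -0.40 ± 0.087, adjusted p = 0.00136).

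At 1 day 32 of 193 miRNAs passed, 20 higher and 12 lower, and 63 (32.6%) had groups that did not overlap against 10% by chance. In the let-7 family 6 of 8 members rose (7 adjusted over the list alone; fry adjusted p = 2.02e-06, and adjusted p = 0.0291 with an estimated correlation), among them mir-84 (0.21 ± 0.045), mir-793 (0.32 ± 0.086) and mir-794 (0.31 ± 0.069). mir-80 (0.18 ± 0.053) and mir-81 (0.21 ± 0.065) rose in the mir-58 family (2 of 5, 2 adjusted over the list alone; fry adjusted p = 0.0104, adjusted p = 0.444 with an estimated correlation), and neither passed with total counts (0.098 and 0.13). mir-44 (-0.14 ± 0.049) and mir-45 (-0.14 ± 0.050), which are nearly identical in sequence, fell (2 of 4 of the mir-44 family, 2 adjusted over the list alone; fry adjusted p = 0.00571, adjusted p = 0.444 with an estimated correlation). Of the 10 stress-associated miRNAs, mir-34 and mir-80 rose (2 adjusted over the list alone; fry adjusted p = 0.04, adjusted p = 0.444 with an estimated correlation), but fry did not pass this list with size factors (adjusted p = 0.275) or with total counts (adjusted p = 0.52), where its direction turned to a fall. The remaining falls included mir-791 of carbon dioxide-sensing neurons (-0.46 ± 0.16), mir-8196a (-0.46 ± 0.12), mir-231 (-0.35 ± 0.084), mir-4813 (-0.31 ± 0.072), mir-49 (-0.31 ± 0.078), mir-43 (-0.26 ± 0.080), mir-51 (-0.26 ± 0.070) and mir-54 (-0.25 ± 0.056). The remaining rises included mir-784 (0.46 ± 0.16), mir-234 (0.38 ± 0.13), mir-357 (0.36 ± 0.093) and mir-230 (0.31 ± 0.084). With total counts 12 were higher and 22 lower. Against the H2O libraries 23 miRNAs passed, 19 of them shared with the DMSO comparison, and 12 of the miRNAs named here no longer did. They were mir-4813 (-0.084), mir-54 (-0.071), mir-49 (-0.12), mir-43 (-0.14), mir-67 (-0.23), mir-231 (-0.19), mir-793 (0.24), mir-80 (0.14), mir-81 (0.16), mir-234 (0.13), mir-784 (0.24) and mir-235 (0.19).

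At 2 days rotenone and DMSO differed in more miRNAs than at any other time, in both directions. mir-788 fell to 0.408 of its DMSO level (log2 -1.29 ± 0.12, adjusted p = 1.34e-10), and mir-244 to 0.525 (log2 -0.93 ± 0.083, adjusted p = 4.65e-11). lsy-6, which sets the left-right difference between the ASE taste neurons, fell to 0.611 (log2 -0.71 ± 0.089, adjusted p = 5.43e-08), and mir-86 to 0.709 (log2 -0.50 ± 0.054, adjusted p = 3.86e-09). let-7 rose 1.4-fold (log2 0.49 ± 0.056, adjusted p = 7.04e-09), from 2366 ± 48.7 CPM (SD, n = 3) in DMSO to 3323 ± 165. mir-240, encoded next to mir-786 of the intestinal defecation rhythm, rose 1.36-fold (log2 0.45 ± 0.058, adjusted p = 1.13e-07).

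At this time 82 of 193 miRNAs passed, 41 higher and 41 lower, of which 10 changed more than 1.5-fold and 3 more than 2-fold, and 46.1% of the 193 had groups that did not overlap (10% by chance). In the let-7 family 6 of 8 members rose and 1 fell (6 and 1 adjusted over the list alone; fry adjusted p = 4.93e-06, adjusted p = 0.205 with an estimated correlation). mir-84 (0.33 ± 0.045), mir-241 (0.40 ± 0.091) and mir-48 (0.26 ± 0.054) were among those that rose, and mir-793, with overlapping groups, fell (log2 -0.25 ± 0.085, adjusted p = 0.0189). Of the 8 lifespan-associated miRNAs, 7 rose (7 adjusted over the list alone; fry adjusted p = 0.000269, adjusted p = 0.255 with an estimated correlation). With total counts 2 of the 7, mir-34 and mir-239a, still rose (fry adjusted p = 0.0134). The 7 were mir-34 (1.16-fold, log2 0.22 ± 0.051, adjusted p = 0.000855), mir-239a (1.19-fold, log2 0.25 ± 0.062, adjusted p = 0.00158), mir-239b (0.25 ± 0.10), mir-71 (0.18 ± 0.064), mir-246 (0.17 ± 0.053), mir-80 (0.16 ± 0.053) and mir-238 (0.16 ± 0.059). As background, loss of mir-239 has been reported to lengthen and loss of mir-71, mir-238 or mir-246 to shorten lifespan, so this list joins miRNAs of opposite known effects. The stress-associated list shares 6 members with it: 6 of 10 rose (8 adjusted over the list alone; fry adjusted p = 1.34e-07, adjusted p = 0.102 with an estimated correlation), and 2 with total counts (fry adjusted p = 0.00209).

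Among miRNAs restricted to neurons 3 of 4 fell at 2 days, lsy-6, mir-790 (-0.53 ± 0.11) and mir-124 (-0.37 ± 0.12) (3 adjusted over the list alone; fry adjusted p = 8.14e-06, adjusted p = 0.205 with an estimated correlation). mir-228, a marker of glia, fell too (log2 -0.48 ± 0.11, adjusted p = 0.000408), while mir-1, a marker of muscle, did not pass (0.018 ± 0.10), nor did mir-60 of the intestine (0.066 ± 0.093). The DMSO libraries of 2 days lay above those of 1 and 3 days for mir-124, with means of 39.5 ± 5.93 CPM against 19.1 ± 1.77 and 17.5 ± 0.922 (SD, n = 3), and rotenone at 2 days (30.5 ± 1.13) lay between. The DMSO means of 2 days were also the highest of these 3 for lsy-6 (89.8 ± 17.6 CPM against 60.4 ± 3.87 and 78.7 ± 4.56) and mir-228 (33070 ± 5838 against 26200 ± 2305 and 26470 ± 3705), and not for mir-790 (83.4 ± 10.6 against 85.6 ± 7.15 and 72.7 ± 3.53). The mirtrons mir-62 (-0.54 ± 0.10) and mir-1018 (-0.71 ± 0.11), which are released by splicing, fell (2 of 3, 2 adjusted over the list alone; fry adjusted p = 1.69e-06, adjusted p = 0.205 with an estimated correlation). In the mir-51 family 4 of 6 fell, mir-52 (-0.38 ± 0.10) the most (4 adjusted over the list alone; fry adjusted p = 0.0047, adjusted p = 0.356 with an estimated correlation). mir-44 (-0.29 ± 0.050) and mir-45 (-0.30 ± 0.050) fell again (2 of 4, 2 adjusted over the list alone; fry adjusted p = 9.45e-06, adjusted p = 0.258 with an estimated correlation). In the mir-58 family 3 of 5 rose, mir-80, mir-81 (0.18 ± 0.065) and mir-82 (0.20 ± 0.078) (3 adjusted over the list alone; fry adjusted p = 0.0131, adjusted p = 0.418 with an estimated correlation), and 1, mir-82, with total counts. In the mir-2 family mir-2 fell (-0.35 ± 0.070) and mir-250 rose (0.18 ± 0.057) (1 higher and 3 lower adjusted over the list alone; fry adjusted p = 0.0247, adjusted p = 0.577 with an estimated correlation), and with total counts 3 fell and 0 rose. The mir-64 family passed fry with TMM (adjusted p = 3.22e-05, adjusted p = 0.255 with an estimated correlation) and not with total counts (adjusted p = 0.131), with 0 of 5 members past the threshold in edgeR (0 adjusted over the list alone). In the lin-4 family mir-237 rose (0.26 ± 0.064; fry adjusted p = 0.209). The mir-35 family had 0 of 8 members past the threshold and an adjusted p of 0.941 in fry.

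The remaining large falls at 2 days were mir-251 (-0.91 ± 0.21), mir-255 (-0.75 ± 0.20) and mir-231 (-0.56 ± 0.081). The rises above 1.3-fold also took in mir-2209a (0.42 ± 0.081), mir-358 (0.42 ± 0.11), mir-78 (0.43 ± 0.10), mir-357 (0.50 ± 0.10) and mir-2210 (0.68 ± 0.16). Larger still were the rises of the rare mir-8203 (0.77 ± 0.26), mir-2953 (1.15 ± 0.39) and mir-8202 (1.36 ± 0.49), with 75, 26 and 21 counts in the DMSO libraries together. With total counts 29 were higher and 46 lower. The DMSO libraries were uneven for the miRNAs with the largest falls, with mir-788 at 60.4, 74.0 and 98.9 CPM. Without DMSO replicate 3 the count was 57, with mir-124 (-0.25), mir-71 (0.15), mir-246 (0.15), mir-80 (0.14), mir-239b (0.21) and mir-238 (0.12) below the threshold.

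**Figure D1:**
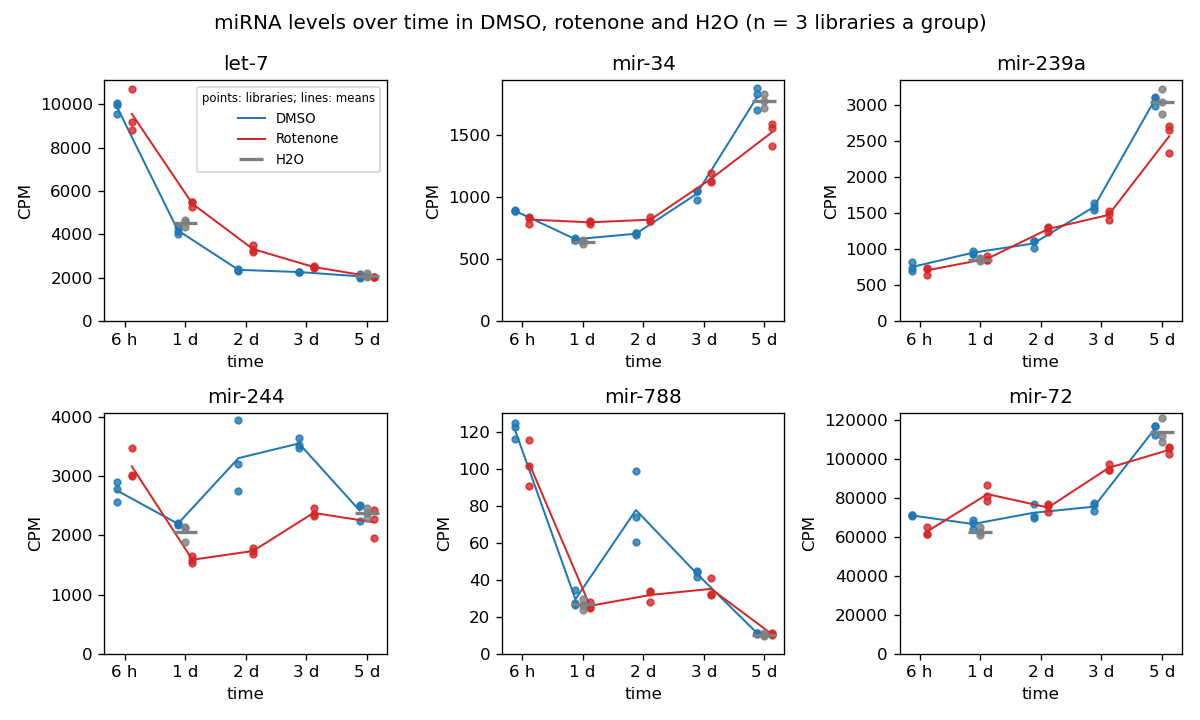
Levels of 6 miRNAs in CPM (vertical axis, from 0) at 6 hours and 1, 2, 3 and 5 days (horizontal axis, evenly spaced), with points for single libraries (n = 3 per group), lines for the means of DMSO (blue) and rotenone (red) and grey bars for the means of H2O. let-7 in rotenone lay above DMSO at 1 and 2 days (5410 against 4184 and 3323 against 2366 CPM), while mir-34 lay below it at 5 days (1517 against 1802 CPM).

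At 3 days the mir-72 family and part of the mir-35 family were higher with rotenone. mir-72, among the most abundant miRNAs of these libraries, rose 1.26-fold (log2 0.34 ± 0.050, adjusted p = 7.2e-06), from 75660 ± 2192 CPM (SD, n = 3) to 95610 ± 1810, and mir-74 rose 1.27-fold (log2 0.35 ± 0.064, adjusted p = 0.000255). mir-39 of the mir-35 family rose 1.31-fold (log2 0.39 ± 0.079, adjusted p = 0.000799). mir-354 rose 2.77-fold (log2 1.47 ± 0.33, adjusted p = 0.00215), with 34 counts in DMSO and 70 in rotenone over 3 libraries each. mir-244 was again lower, at 0.67 of its DMSO level (log2 -0.58 ± 0.083, adjusted p = 6.04e-06), as was mir-1832a at 0.72 (log2 -0.47 ± 0.10, adjusted p = 0.00132).

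Of the 193 miRNAs 24 passed at 3 days, 16 higher and 8 lower, and 28% had groups that did not overlap (10% by chance). In the mir-72 family 3 of 3 members rose (3 adjusted over the list alone; fry adjusted p = 8.03e-06, adjusted p = 0.0766 with an estimated correlation), 2 of them with total counts, and mir-73 (0.28 ± 0.10) had overlapping groups. In the mir-35 family 4 of 8 rose, mir-38 (0.43 ± 0.11), mir-39, mir-42 (0.38 ± 0.10) and mir-36 (0.30 ± 0.091) (4 adjusted over the list alone; fry adjusted p = 0.0217, adjusted p = 0.388 with an estimated correlation). With total counts 3 rose and the list did not pass (fry adjusted p = 0.0841). Its share of all counts was 14.4% ± 1.5 in rotenone and 12.9% ± 0.26 in DMSO (SD, n = 3). mir-43 (0.35 ± 0.083), mir-1829a (0.44 ± 0.12), mir-2209a (0.31 ± 0.082) and mir-34 (1.12-fold, log2 0.16 ± 0.051, adjusted p = 0.0274) also rose. mir-237, the sister of lin-4, fell (log2 -0.22 ± 0.064, adjusted p = 0.0207), as did mir-791 (-0.60 ± 0.17), mir-85 (-0.24 ± 0.070), mir-355 (-0.22 ± 0.068), mir-246 (-0.16 ± 0.053) and the rare mir-8212 (-1.01 ± 0.35). With total counts 9 were higher and 25 lower, and with DESeq2 size factors 15 and 12. Leaving out rotenone replicate 2 or DMSO replicate 1 left 10 or 12 miRNAs, and mir-34 lost its call with total counts (0.072).

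At 5 days 2 miRNAs differed between rotenone and DMSO, and both were lower with rotenone. mir-34 fell to 0.842 of its DMSO level (log2 -0.25 ± 0.051, adjusted p = 0.00432): it stood at 1701 to 1876 CPM in the DMSO libraries, 1715 to 1828 in H2O and 1409 to 1585 in rotenone. mir-239a fell to 0.836 (log2 -0.26 ± 0.062, adjusted p = 0.0194), with 2994 to 3121 CPM in DMSO, 2882 to 3222 in H2O and 2343 to 2712 in rotenone. Both also passed against the H2O libraries of 5 days, mir-34 at -0.22 ± 0.051 (adjusted p = 0.0193) and mir-239a at -0.25 ± 0.062 (adjusted p = 0.0311). The next 3 by p-value, mir-2216 (-0.80 ± 0.28), mir-259 (-0.29 ± 0.10) and mir-72 (-0.14 ± 0.050), had an adjusted p of 0.278. At an unadjusted p under 0.05 stood 24 of 193 miRNAs, and 16.1% had groups that did not overlap (10% by chance). Of the stress-associated miRNAs 2 of 10 fell (3 adjusted over the list alone; fry adjusted p = 8.27e-05, adjusted p = 0.0111 with an estimated correlation). Of the lifespan-associated miRNAs the same 2 of 8 fell (3 adjusted over the list alone; fry adjusted p = 0.012, adjusted p = 0.139 with an estimated correlation). With total counts neither list passed (fry adjusted p = 0.143 for both, 0 members), and with size factors both did (0.0308) with 1 member each. edgeR with total counts, without the filter or on these 6 libraries alone passed 0 miRNAs (18, 19 and 11 at an unadjusted p under 0.05). DESeq2, fitted to all 36 libraries, passed both mir-34 and mir-239a. Neither passed without DMSO replicate 3 (mir-34 -0.23, mir-239a -0.25) or rotenone replicate 1 (-0.21, -0.29). mir-239a did not pass with DESeq2 size factors (-0.24), without DMSO replicate 2 (-0.26) or without rotenone replicate 3 (-0.20).

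**Figure D2:**
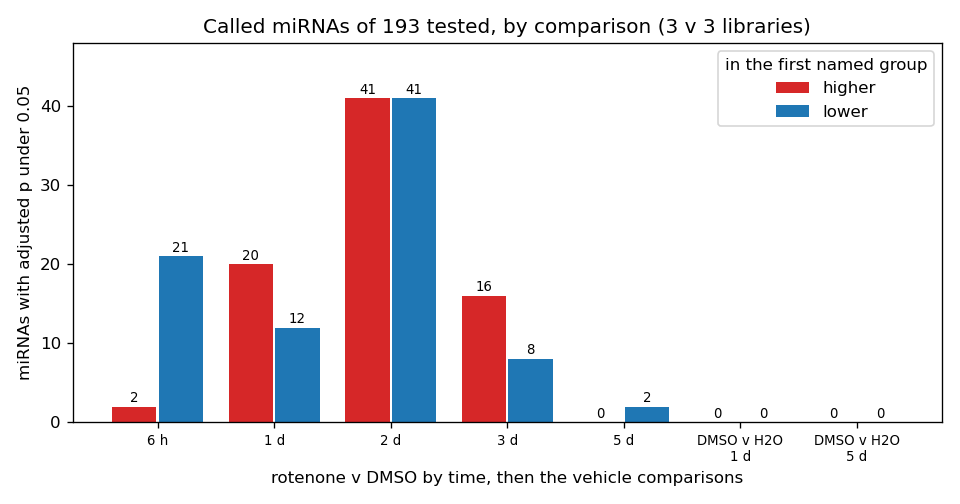
Number of miRNAs of 193 with an adjusted p under 0.05 (vertical axis, from 0) in the rotenone against DMSO comparisons by time and in the DMSO against H2O comparisons (horizontal axis), higher (red) and lower (blue) in the first named group, 3 libraries a group. At 2 days 41 were higher and 41 lower, against 0 and 2 at 5 days; with total counts the numbers at 6 hours were 5 and 5 in place of 2 and 21.

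Averaged over the 5 times, let-7 was 1.14-fold higher with rotenone (log2 0.19 ± 0.025, adjusted p = 4.01e-07), though its change was not of 1 sign at all times. mir-794 of the same family rose 1.14-fold (log2 0.19 ± 0.031, adjusted p = 2.84e-05), with no difference at 6 hours (-0.0011), and mir-358 1.14-fold (log2 0.19 ± 0.051, adjusted p = 0.00595). mir-86 was lower at all 5 times, at 0.877 of its DMSO level on average (log2 -0.19 ± 0.024, adjusted p = 2.52e-07). So were mir-355 (0.882, log2 -0.18 ± 0.031, adjusted p = 3.5e-05), mir-788 (0.749, log2 -0.42 ± 0.068, adjusted p = 1.87e-05), mir-8196a (-0.26 ± 0.058), mir-1820 (-0.10 ± 0.036) and mir-79 (-0.094 ± 0.032). In total 43 of 193 miRNAs passed, 16 higher and 27 lower, and 8 of the 43 had mean log CPM on the same side at each time. Of all 193 miRNAs 14 (7.25%) had this, and some miRNAs would share a side at all 5 times by chance. The share alone is therefore no evidence of a change kept over the times. In the let-7 family 5 of 8 rose (5 adjusted over the list alone; fry adjusted p = 7.44e-05, adjusted p = 0.143 with an estimated correlation). In the mir-51 family 4 of 6 fell, among them mir-54 (-0.13 ± 0.025) (5 adjusted over the list alone; fry adjusted p = 0.00209, adjusted p = 0.506 with an estimated correlation). mir-44 (-0.075 ± 0.022) and mir-45 (-0.077 ± 0.022) fell (2 adjusted over the list alone; fry adjusted p = 0.00252, adjusted p = 0.506 with an estimated correlation). Of the mirtrons mir-1018 fell (-0.16 ± 0.059) (2 adjusted over the list alone; fry adjusted p = 0.00209, adjusted p = 0.506 with an estimated correlation). Of the neuronal miRNAs lsy-6 fell (-0.16 ± 0.042) (2 adjusted over the list alone; fry adjusted p = 0.0374, adjusted p = 0.566 with an estimated correlation). The glial marker mir-228 was lower (log2 -0.21 ± 0.047, adjusted p = 0.00128), while mir-1 (0.013 ± 0.044) and mir-60 (-0.020 ± 0.042) passed in none of the rotenone comparisons, averaged or single. mir-54, mir-44, mir-45 and mir-1018 had higher means with rotenone at 3 and 5 days, lsy-6 at 6 hours and 5 days, and mir-228 at 1 day. A model of treatment, time and lane passed 20 miRNAs (5 higher, 15 lower). The mean without 2 days, chosen after seeing the data, passed 11, of which 9 were among the 43. The falls of mir-44 (-0.022), mir-45 (-0.021), mir-1018 (-0.022), lsy-6 (-0.021), mir-788 (-0.20), mir-228 (-0.14), mir-1820 (-0.077) and mir-79 (-0.070) and the rise of mir-358 (0.13) no longer passed in it. With total counts 12 were higher and 37 lower. Without the times that use lane 8, also chosen after seeing the data, 34 passed and mir-41 (0.031) and mir-72 (-0.044) changed sign.

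The change with rotenone itself differed between the 5 times for 87 of 193 miRNAs (F-test on 4 differences; 102 at an unadjusted p under 0.05). mir-244 was 0.20 ± 0.082 at 6 hours, -0.47 ± 0.083 at 1 day, -0.93 ± 0.083 at 2 days, -0.58 ± 0.083 at 3 days and -0.13 ± 0.083 at 5 days (adjusted p = 2.81e-08). mir-72 fell at 6 hours (-0.18 ± 0.050) and rose at 1 and 3 days (0.30 ± 0.050 and 0.34 ± 0.050; adjusted p = 1.69e-07). mir-34 rose at 1, 2 and 3 days and fell at 5 days (adjusted p = 6.48e-07). let-7 stood at -0.044 ± 0.055 at 6 hours, 0.49 ± 0.056 at 2 days and -0.023 ± 0.056 at 5 days (adjusted p = 1.28e-06). mir-74 fell at 6 hours and rose at 3 days (adjusted p = 1.86e-06). Of the tissue markers mir-228 differed between times (adjusted p = 0.0348), and mir-1 (adjusted p = 0.999) and mir-60 (adjusted p = 0.226) did not pass.

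The vehicle comparison asks whether DMSO itself moved miRNA levels against H2O. No miRNA passed in edgeR at either time, 0 of 193 at 1 day and 0 at 5 days, with 14 and 8 at an unadjusted p under 0.05. DESeq2 called 1 miRNA at 1 day, mir-54 (0.18, DMSO higher), and 0 at 5 days. At 1 day the smallest p-values were those of mir-54 (0.18 ± 0.056, adjusted p = 0.252), mir-4813 (0.23 ± 0.072, adjusted p = 0.252) and mir-74 (0.17 ± 0.063, adjusted p = 0.425), followed by the rarer mir-4936 (0.37 ± 0.14) and mir-1824 (1.10 ± 0.41). At 5 days they were those of mir-234 (-0.49 ± 0.17), mir-240 (-0.15 ± 0.058), mir-4813 (0.23 ± 0.10), mir-1018 (-0.38 ± 0.16) and mir-253 (0.16 ± 0.068), all with an adjusted p of 0.905. mir-1, mir-60 and mir-228 had adjusted p-values of 0.829 or more at both times, and fry passed 0 of the 13 lists (1 and 0 at an unadjusted p under 0.05; camera passed 0). The median SE over miRNAs was 0.097 at 1 day and 0.12 at 5 days.

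Time changed most miRNAs. In DMSO let-7 went from 9845 ± 261 CPM (SD, n = 3) at 6 hours to 4184 ± 156 at 1 day and 2067 ± 88 at 5 days (F-test adjusted p = 2.57e-31). The mir-35 family, with mir-35 at 8484 ± 797 CPM at 6 hours and 42080 ± 1963 at 1 day, rose from 2.46% ± 0.052 to 12.3% ± 0.56 of all counts and stood at 9.7% ± 0.41 at 5 days. mir-34 went from 658 ± 9.82 CPM at 1 day to 1802 ± 90.9 at 5 days. The F-test over the 5 times in DMSO passed 173 of 193 miRNAs.

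Between 1 and 5 days, averaged over DMSO, H2O and rotenone, 6 of the 8 lifespan-associated miRNAs rose and let-7 and mir-237 fell. Within each treatment these times ran on different lanes. mir-239a rose 3.24-fold (log2 1.70 ± 0.037, adjusted p = 1.29e-31), mir-238 2.61-fold (log2 1.38 ± 0.035, adjusted p = 3.88e-30), mir-34 2.44-fold (log2 1.29 ± 0.030, adjusted p = 6e-31) and mir-80 1.92-fold (log2 0.94 ± 0.031, adjusted p = 2.58e-26). mir-1832a rose 4.48-fold (log2 2.16 ± 0.064, adjusted p = 7.12e-28) and mir-355 3.34-fold (log2 1.74 ± 0.041, adjusted p = 6e-31). let-7 fell to 0.442 of its level at 1 day (log2 -1.18 ± 0.033, adjusted p = 7.27e-29), mir-237 to 0.388 (log2 -1.37 ± 0.038, adjusted p = 7.27e-29) and mir-4813 to 0.259 (log2 -1.95 ± 0.048, adjusted p = 2.98e-30). The muscle marker mir-1 fell to 0.556 (log2 -0.85 ± 0.057, adjusted p = 2.68e-16), mir-228 fell (-0.26 ± 0.060), and mir-60 did not pass (0.058 ± 0.054, adjusted p = 0.333).

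Of 193 miRNAs 140 passed between 1 and 5 days, 63 higher and 77 lower at 5 days, with 70 above 1.5-fold and 43 above 2-fold. fry passed all 13 lists and camera with an estimated correlation 0 (2 at an unadjusted p under 0.05). Of the lifespan-associated miRNAs 6 of 8 rose (6 adjusted over the list alone; fry adjusted p = 8.68e-23, adjusted p = 0.137 with an estimated correlation), and with total counts 6 rose and 2 fell. Of the stress-associated miRNAs 8 rose and 1, mir-229 (-0.35 ± 0.028), fell (8 and 1 adjusted over the list alone; fry adjusted p = 3.24e-24, adjusted p = 0.0536 with an estimated correlation), and with total counts 7 rose and 3 fell. In the mir-35 family 7 of 8 fell (7 adjusted over the list alone; fry adjusted p = 5.71e-09, adjusted p = 0.486 with an estimated correlation), among them mir-42 (-1.24 ± 0.058) and mir-41 (-0.79 ± 0.052). The let-7 family split, with mir-84 (0.82 ± 0.026) and mir-48 (0.56 ± 0.031) among 3 that rose and let-7 and mir-241 (-0.52 ± 0.053) among 4 that fell (3 and 4 adjusted over the list alone). Its median was 0.029 and its mean -0.0035, and fry put it up (adjusted p = 0.0356, adjusted p = 0.795 with an estimated correlation) with TMM and down with total counts. In the mir-64 and mir-44 families, whose direction also turned with total counts, 4 of 5 rose and 1 fell, and 3 of 4 rose and 1 fell (the same numbers adjusted over the list alone; adjusted p = 0.486 and 0.521 with an estimated correlation). With total counts fry did not pass either family (adjusted p = 0.438 and 0.252). In the mir-58 family mir-80, mir-58a (0.51 ± 0.041) and mir-82 (0.19 ± 0.045) rose (3 adjusted over the list alone; adjusted p = 0.486 with an estimated correlation), and with total counts 2 rose and 2 fell. In the mir-2 family mir-43 (-1.31 ± 0.052), mir-797 (-1.13 ± 0.11) and mir-2 (-0.49 ± 0.041) fell (3 adjusted over the list alone; adjusted p = 0.486 with an estimated correlation). The 3 mirtrons and 3 of the 4 neuronal miRNAs fell, while mir-791 rose (0.39 ± 0.094) (3, 3 and 1 adjusted over the list alone; adjusted p = 0.486 and 0.521 with an estimated correlation). The mir-51 family had 2 members higher and 4 lower, the mir-72 family 1 and 2, and the lin-4 family 1 lower (the same numbers adjusted over the list alone; adjusted p = 0.508, 0.767 and 0.486 with an estimated correlation). mir-2221 had 5 and 62 counts in DMSO at 1 and 5 days, and mir-8192 35 and 3. Total counts in place of TMM moved the median change of all miRNAs from -0.030 to -0.20 and the split to 48 higher and 99 lower. lin-4 did not pass with TMM and fell with total counts (-0.27).

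Within lane 1, DMSO at 5 days against 2 days passed 131 of 193 miRNAs, 64 higher and 67 lower. mir-239a rose 2.85-fold (log2 1.51 ± 0.064, adjusted p = 3.37e-22), mir-34 2.56-fold (log2 1.36 ± 0.052, adjusted p = 1.95e-23) and mir-253 2.66-fold (log2 1.41 ± 0.069, adjusted p = 2.9e-20). mir-786 rose 2.53-fold (log2 1.34 ± 0.092, adjusted p = 8.32e-16), and mir-788 fell to 0.143 (log2 -2.80 ± 0.16, adjusted p = 5.97e-18). In DMSO mir-788 stood at 77.8 ± 19.5 CPM at 2 days, against 29.45 ± 4.42 at 1 day, 43.5 ± 1.90 at 3 days and 11.1 ± 0.244 at 5 days (SD, n = 3). Its fall from 2 days was thus larger than that from 1 or 3 days. Of the stress-associated miRNAs 8 rose and 1 fell (8 and 1 adjusted over the list alone; fry adjusted p = 9e-20, adjusted p = 0.0438 with an estimated correlation). Of the lifespan-associated miRNAs 7 of 8 rose (7 adjusted over the list alone; fry adjusted p = 5.23e-18, adjusted p = 0.0915 with an estimated correlation). Of the 4 neuronal miRNAs 3 fell, mir-124 the most (-1.65 ± 0.15; 3 adjusted over the list alone; fry adjusted p = 9.4e-10, adjusted p = 0.308 with an estimated correlation). In DMSO mir-124 stood higher at 2 days (39.5 ± 5.93 CPM, SD, n = 3) than at 1 and 3 days (19.1 ± 1.77 and 17.5 ± 0.922). The median change of the neuronal list was -1.12 here and -0.46 at 5 days against 1 day averaged over treatments. With total counts 43 were higher and 90 lower, at a median of all miRNAs of -0.33 against -0.059, and lin-4 turned from a rise with overlapping groups (0.24 ± 0.10) to -0.030.

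Within lane 8, rotenone at 3 days against 1 day passed 82 miRNAs, 41 in each direction. let-7 fell to 0.462 (log2 -1.12 ± 0.056, adjusted p = 7.41e-19), mir-237 to 0.451 (log2 -1.15 ± 0.065, adjusted p = 1.7e-17), and mir-239a rose 1.7-fold (log2 0.77 ± 0.063, adjusted p = 4.58e-13). In the mir-44 family 3 of 4 rose (fry adjusted p = 8.51e-07, camera 0.529). Of the 10 stress-associated miRNAs 3 rose and 2 fell (fry adjusted p = 1.52e-05, camera 0.566), and of the 3 mirtrons 2 rose (fry adjusted p = 0.015, camera 0.784). These numbers of members were the same adjusted over the list alone. In the let-7 family 5 of 8 fell (5 adjusted over the list alone; fry adjusted p = 7.71e-10, adjusted p = 0.357 with an estimated correlation). Both members of the lin-4 family fell (2 adjusted over the list alone; fry adjusted p = 1.94e-10, adjusted p = 0.357 with an estimated correlation). Of the lifespan-associated miRNAs mir-239a, mir-238 (0.57 ± 0.060), mir-34 (0.53 ± 0.052) and mir-80 (0.38 ± 0.053) rose, and lin-4 (-0.53 ± 0.10) and mir-246 (-0.15 ± 0.053) fell (4 and 2 adjusted over the list alone; fry adjusted p = 2.62e-06, adjusted p = 0.529 with an estimated correlation).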

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

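The counts of other splits, and the tests below on lanes, on normalization, on the DMSO libraries of 2 days and on the H2O controls, were chosen only after the results they bear on had been seen; the test on depth was chosen before.

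The rotenone change differed between the 5 times for 87 miRNAs in an F-test of the differences. The highest and the lowest of the 5 changes lay apart by 1.13 on the log2 scale for mir-244, 0.52 for mir-72, 0.52 for mir-34, 0.53 for let-7, 0.74 for mir-74, 0.43 for mir-84, 0.83 for mir-2209a, 0.64 for mir-1829b, 0.57 for mir-240 and 1.23 for mir-788. Among the lifespan-associated miRNAs that range was 0.50 for mir-239a, 0.33 for mir-246, 0.31 for mir-80, 0.27 for mir-238 and 0.50 for mir-239b.

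Opposite directions at different times were the first pattern weighed, since mir-72, mir-74 and mir-2209a fell at 6 hours, when DMSO was on lane 8, and rose at 3 days, when rotenone was. Total counts in place of TMM kept 74 of the 87 calls, so most of them do not hinge on the choice between these scalings. Total counts do not correct for composition, so this cannot exclude composition as a cause. The difference between 2 and 5 days, where no library was on lane 8, passed for 53 miRNAs, so by design lane 8 cannot be the source of that part. Of these, let-7 (0.51 ± 0.079, adjusted p = 8.85e-06), mir-34 (0.46 ± 0.072, adjusted p = 8.85e-06), mir-244 (-0.80 ± 0.12, adjusted p = 5.86e-06) and mir-72 (0.19 ± 0.071, adjusted p = 0.0381) passed, and mir-74 did not (0.034 ± 0.091, adjusted p = 0.838). Rotenone was on lane 2 at 2 days and on lane 3 at 5 days, with DMSO on lane 1 both times. Lanes 2 and 3 therefore stay open for these 53. DMSO (lane 2) against H2O (lane 3) at 1 day passed 0 miRNAs, but was not examined for the 53. For 6 hours against 1 and 3 days, lane 8 and treatment cannot be told apart: across miRNAs, which are not independent replicates, the changes correlated at -0.26 (95% bootstrap interval -0.47 to 0.0022; Spearman -0.13), and in the additive model lane 8 differed from lane 1 for 15 miRNAs, among them mir-244 (-0.43 ± 0.088, adjusted p = 0.000608), mir-2209a (0.41 ± 0.070), mir-74 (0.32 ± 0.059), mir-1829b (0.31 ± 0.054) and mir-72 (0.21 ± 0.041). That model has no term for a rotenone change that differs between times. Its lane term therefore takes up such differences and is no separate evidence for lane 8. A dependence of the rotenone response on time stays open beside the lanes as the biological explanation that the design names.

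The 82 calls at 2 days were the second pattern. Lanes 1 and 2, on which these groups ran, also held DMSO and H2O of 5 days, and there the same 82 miRNAs moved by a median of -0.0076 in the direction of the calls (95% bootstrap interval -0.026 to 0.024) against 0.30 at 2 days, which argues against the lanes. With every library thinned to 4361246 counts 61 miRNAs passed, and 64 to 75 in 20 further draws added later, which argues against depth. For 63 of the 82 (76.8%, 95% exact interval 66.2 to 85.4) the DMSO mean of 2 days lay farther than the rotenone mean from the midpoint of DMSO at 1 and 3 days, so DMSO libraries off their own time course may account for part of the calls. The exact interval and the bootstrap interval above treat miRNAs as independent, which they are not, so both are likely too narrow. An effect of rotenone at this time stays open.

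Lower mir-34 and mir-239a at 5 days were the third pattern, and 2 of 2 passed against the H2O libraries as well, which argues against the DMSO control as the cause. Lane 3 held rotenone at 5 days, and between the vehicles of 1 day, on lanes 2 (DMSO) and 3 (H2O), mir-34 differed by 0.046 ± 0.051 and mir-239a by 0.15 ± 0.063 (adjusted p = 0.772 and 0.425, DMSO higher). This lane stays open, more so for mir-239a, as does an effect of rotenone.

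Splits of the 6 libraries of a comparison are too few for a share under 0.05. The real split gave 23 miRNAs at 6 hours and the highest of the others 7, with 32 and 2 at 1 day, 82 and 6 at 2 days, 24 and 2 at 3 days, 2 and 1 at 5 days, 131 and 0 for 5 against 2 days in DMSO, and 82 and 0 for 3 days against 1 day in rotenone. In each of these 1 of 10 splits, the real one, reached the count, and in both vehicle comparisons all 10 did, at 0 miRNAs for the real split and 0 for the highest other. The real split also gave the most miRNAs for the mean over times (43, highest other 12) and the difference between times (87, highest other 39). So it did for time in DMSO (173, highest other 128) and 5 days against 1 day (140, highest other 93). In each, 1 of 100 splits, the real one, gave as many, so a random division of these libraries rarely gives such counts. The splits cannot exclude chance differences between cultures or lanes, since the libraries of a group shared a lane and may be technical replicates.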

How the results depend on the processing

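The mean over times without 2 days or without lane 8 and the 20 further draws of the thinning were chosen after seeing the data; the other settings were chosen before their results were seen. At 1 and 2 days, for the difference between times and for the comparisons of times, counts of miRNAs stayed within 1.5 times under every setting run, except in the thinning at 1 day (32), which gave 28, and 21 to 30 in the further draws. A fit of the compared groups alone rests on fewer libraries, and no filter means 241 hairpins tested in place of 193. For the other changes below the cause was not tested.

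At 6 hours (23 miRNAs) DESeq2 size factors gave 13, total counts 10 (7 shared), no filter 8 and only the groups compared 0 (24 at an unadjusted p under 0.05). DESeq2 on all 36 libraries called 20. Leaving out 1 library gave 10 to 17 (DMSO replicates 1, 2 and 3: 13, 10 and 13; rotenone replicate 1: 12), and thinning 8 (5 to 26 in 20 further draws). At 3 days (24) leaving out 1 library gave 10 to 21 (rotenone replicate 2: 10; DMSO replicate 1: 12) and thinning 22 (14 to 24). At 5 days (2) size factors gave 1, and total counts, no filter and only the groups compared 0 each (18, 19 and 11 at an unadjusted p under 0.05). DESeq2 on all 36 libraries called 2. Leaving out 1 library gave 0 to 3 (without DMSO replicate 2 or 3: 1 or 0; rotenone replicate 1 or 3: 0 or 1), and thinning 1 (0 to 3). For DMSO against H2O at 1 day DESeq2 gave 1 where edgeR gave 0. The mean over times (43) gave 20 with lane in an additive model, which gave 23 without that term and 30 miRNAs for lane itself, and 11 without 2 days (9 shared).

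Signs were compared for named miRNAs past the threshold in either fit. They turned with total counts for mir-250 (-0.12), mir-44 (-0.11) and mir-45 (-0.080) at 5 days against 1 day and lin-4 (-0.030) at 5 against 2 days in DMSO. Without lane 8 they turned for mir-41 (0.031) and mir-72 (-0.044) in the mean over times.

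Of the 13 lists, camera with an estimated correlation passed 0 at 6 hours (fry 5), 1 at 1 day (4), 0 at 2 days (10), 0 at 3 days (2), and 1 at 5 days (2). It passed 0 in the mean over times (5), 0 at 5 days against 1 day (13), 1 at 5 against 2 days in DMSO (12) and 0 at 3 days against 1 day in rotenone (6). fry passed 2 lists at 6 hours with size factors and 0 with total counts, which gave 8 at 1 day, 5 at 3 days and 0 at 5 days.

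Replicate numbers did not pair the libraries: deviations from the group means correlated at -0.0094 on average for the same number and 0.0047 for other numbers, 4 of 15 pairs exceeded 0.1, and 9 of 36 libraries correlated best with their own number. With the replicate number as a block the counts were 23 at 6 hours, 33 at 1 day, 86 at 2 days, 25 at 3 days, 2 at 5 days and 46 for the mean, and fry passed 7 lists at 1 day.

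Over all named miRNAs and settings other than a library left out, 4357 values kept their side of the threshold, 203 no longer passed and 71 newly passed. A further 165, below the threshold, shifted by more than 1 SE, and 6 past the threshold in either fit turned sign. With a library left out these numbers were 7827, 317, 42, 70 and 0. The sign was not checked for values below the threshold in both fits, and F-tests have none. Low counts limit the rare miRNAs: mir-8190 had 2 counts in rotenone and 13 in DMSO at 6 hours.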

Other observations

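The tests in this part were chosen only after the data had been seen. The rotenone changes at 1 and 2 days correlated across the 193 miRNAs at r = 0.38 (Spearman 0.41), those at 6 hours and 5 days at 0.33 (Spearman 0.099), and those at 6 hours and 1 day at -0.24 (Spearman 0.029), from 10 pairs of times. These are correlations across miRNAs, which are not independent replicates.

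In DMSO several miRNAs of abundant families parted over time. mir-237 went from 43360 ± 1267 CPM (SD, n = 3) at 6 hours to 13290 ± 438 at 5 days and mir-238 from 7940 ± 168 to 19940 ± 188. mir-80 went from 45010 ± 1850 to 89960 ± 3818 and mir-72 from 71090 ± 159 to 115600 ± 2851. mir-84, of the let-7 family, stood at 5453 ± 175 at 6 hours, 2476 ± 58.9 at 2 days and 6102 ± 174 at 5 days, while let-7 itself stood at 2366 ± 48.7 at 2 days and 2067 ± 88 at 5 days. mir-1 went from 634 ± 58.3 at 6 hours to 351 ± 56.1 at 5 days.

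Higher let-7 with rotenone at 1 and 2 days, when let-7 fell in DMSO, led to the hypothesis that rotenone slows the time course, which would set the change at 2 days against the change from 1 to 3 days in DMSO. Across the 193 miRNAs this correlation was -0.025 (95% bootstrap interval -0.21 to 0.16; Spearman -0.083), and 9 of the 20 labelled splits of the libraries of 2 days were as negative. Over the 82 miRNAs called at 2 days the correlation was -0.22, and 46 of them ran against the DMSO change. With the rotenone change from 1 to 3 days it was -0.17 across the 193. The bootstrap interval lies above the value set for a slower course but does not clear the bound set against it, so the data leave the hypothesis undecided.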
